A study of Mus musculus with 23 samples.

How the data were processed

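Immunoglobulin heavy chain transcripts were sequenced from the bone marrow and the spleen of C57BL/6J mice immunized 4 times with phosphate-buffered saline (PBS), ovalbumin alone (OVA alone), ovalbumin with CpG or ovalbumin with Alum, and the tissues were taken a week after the last immunization, per the labels' protocols and the series description. Total RNA was isolated from cell suspensions with RNAzol, and cDNA was made by 5′ rapid amplification of cDNA ends with template-switching oligonucleotides that carry unique molecular identifiers, per the labels' protocols. The libraries were read as paired ends on an Illumina instrument and preprocessed with the submitters' own pipeline, per the series description. Trimmomatic and Bowtie2 are named without versions in the submitters' processing notes. The program that assigned the V, D and J genes and grouped sequences into clones is not given in the sources used here.

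In all, 145 tables from 23 libraries were analysed, 12 of bone marrow and 11 of spleen. Each treatment had 3 libraries per tissue except OVA alone in the spleen, which had 2; the spleen library of OVA alone 5 was not analysed here. Libraries are named by tissue, treatment and the number in their title (PBS 1 to 3, OVA alone 4 to 6, OVA + CpG 10 to 12, OVA + Alum 13 to 15). Clone, clone assignment, recombination and mutation tables were used for IgG in all 23 libraries. For IgM, clone, clone assignment and recombination tables were used for 10 libraries and mutation tables for 23.

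Clone sizes were deposited by the authors as counts of sequences per clone, and V bases and V substitutions as counts per sequence. The mutation frequency was deposited as a fraction per sequence, equal to the V substitutions over the V bases after a discounted length was taken off, and a smoothed fraction averaged per clone stood beside it. CDR3 lengths were deposited in nucleotides, and mutation positions were deposited as positions in the V gene counted from 0; both fall under other units. Names of sequences carry a number in parentheses whose meaning is not given in the sources used here, and only 0.458% to 11.0% of the names per IgG library carry a 16-base identifier, so sequences were taken as deposited and not collapsed by identifier. The depth was 83212 IgG sequences, 695 to 13150 per library, of which 83004 lay in 6865 clones (123 to 757 per library), and 200911 IgM sequences in the 10 libraries, 4626 to 49852 per library. Single-sequence clones made up 26.6% to 74.0% of the IgG clones of a library. Intervals for shares of sequences are Wilson intervals at the 95% level and cover counting error only, since sequences without identifiers are not independent molecules.

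From these tables, 5 values were computed per library. The mutation frequency is the mean over clones of the mean percent of V bases substituted in the sequences of each clone. The CDR3 length is the mean over clones in nucleotides. Clonal diversity is the exponential of the Shannon entropy, an effective number of clones, over 655 sequences drawn from every IgG library and averaged over 200 draws. The largest clone share is the percent of the drawn sequences that belong to the 10 largest clones. Selection strength is log2 of the ratio of replacement to silent mutations in CDR1 and CDR2 over the same ratio in the framework regions, with each distinct mutation counted once per clone. The deposited amino acid columns were possible for the codon position in only 12.8% of cases and were not used. Germline codons were rebuilt instead from 372837 deposited substitutions, which gave 3302 codons of 103 alleles with 0 stop codons in the reading frame used and 184 and 229 in the other frames. With them, 73.8% of the distinct IgG mutations were classified. The mutation tables cover the V gene up to framework 3, so a version of selection strength with CDR3 could not be computed. The planned version with 1 added to each of the 4 counts was computed as an alternative.

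IGHV gene usage was tested on clone numbers per gene, so that an expanded clone counts once, with the quasi-likelihood test of edgeR 4.0.16 (TMM normalization, its filter on low counts, limma 3.58.1, R 4.3.3) and DESeq2 1.42.0 as an alternative. All 8 groups were fitted together with 1 mean each and a shared estimate of the spread. Libraries that share clones therefore also enter the spread used for the other groups. The filter left 10 genes in the IgG comparisons and 36 in the comparison of isotypes. Library totals were then taken over the genes left. The log2 differences are therefore relative to the tested genes and can differ from the ratio of the printed shares, which are of all clones. For the 5 values per library, bone marrow and spleen were compared by a two-sided permutation test that permutes tissue within each treatment (100000 resamples, or every arrangement where a group had under 10 libraries), the 4 treatments by a permutation test of the F statistic, and adjuvanted against unadjuvanted libraries by a two-sided exact permutation test. These made a family of 25 tests with Benjamini-Hochberg adjustment, and a result was called at an adjusted p under 0.05. For an alternative, its p-value replaced that of the main test, and the other tests of the family kept their main p-values. IGHJ genes (4 tests) and IGHV families with the fixed gene lists (18 tests) were compared by the same permutation within treatments. IgM and IgG of the same library were compared by exact sign flips, and in edgeR with the library as a block. Differences of the adjuvant effect between tissues (5 tests) and further mutation and junction measures (18 tests) were not planned. Their alternatives were adjusted like those of the 25 tests. Sharing was counted on clones with the same IGHV gene, IGHJ gene and CDR3 nucleotides, or amino acids for clonotypes. The other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, biopython 1.88 and matplotlib 3.10.9.

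The tests, the gene lists, the genes to be named and most alternatives were fixed before the data were examined. The lists were the IGHV families, the families nearest the D genes (IGHV2 and IGHV5), genes associated with B-1 cells (IGHV11-1, IGHV11-2, IGHV12-3), the phosphorylcholine gene IGHV7-1, to which no clone was assigned, and IGHV1-72, known from responses to the hapten NP. Named genes are up to 15 higher and 15 lower called genes per IGHV comparison, and in the tissue comparison also the 10 genes with the largest mean share of clones and every tested gene of the lists. Naming was also allowed for the largest clone of each library, of which a part is named, and for up to 10 clonotypes found under most library numbers. Alternatives were other counting units, filters, normalization, tests and diversity measures, each library left out in turn, and the title number as a block. Some alternatives were chosen only after seeing the data: substitutions over all V bases, alleles with an unusual framework 2 label left out, CDR3 over 100 nucleotides left out, clones found under another title number left out, the same without the 2 libraries that then keep fewer than 20 clones, and comparisons without the adjuvanted bone marrow libraries and, for the tissues, spleen OVA alone 4, which leaves 6 bone marrow and 4 spleen libraries for the permutation within treatments.

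Libraries of a group were compared with each other by chi-square tests of IGHV gene usage. By sequences, which are not independent molecules, all 22 pairs differed. By clones, 9 of the 22 pairs differed at the 5% level, and the 6 pairs within CpG or within Alum in bone marrow did not. In those 6 pairs at most 76.6% of the clones of the smaller library were shared, so no libraries were merged. The tests were tested on simulated data. For the permutation tests, independent values were drawn. Without a shift, 3.2% to 6.6% of 500 simulations gave an unadjusted p under 0.05. With a shift of 2 SD, 99.0% did for the tissues, and 84.6% and 82.4% for adjuvant in bone marrow and spleen. It was 46.8% and 47.0% for the 4 treatments, 100% for the isotypes and 51.8% for the difference of adjuvant effects. Results were called on adjusted p-values, which are at least as large, and the adjuvanted bone marrow libraries share clones. These percentages therefore do not hold for the calls made here. With the filter on low counts, edgeR recovered 69.4% of genes changed 2-fold and 100% of those changed 4-fold between tissues, 71.9% and 100% for adjuvant in bone marrow, and 33.3% and 94.4% for CpG against Alum in bone marrow, where about 10 genes were tested in each of 20 simulations. False calls per simulation between tissues were 0.1 at 2-fold and 0.65 at 4-fold. Without the filter, recovery in the same 3 comparisons was 33.9%, 13.2% and 5.71% at 2-fold and 91.8%, 77.1% and 50.7% at 4-fold. With sequences counted it was 1.49%, 0.758% and 0% at 2-fold and 22.6%, 3.47% and 1.09% at 4-fold.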

Results

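The heavy chain repertoire of immunized mice was read as IgG and IgM transcripts from bone marrow, where long-lived plasma cells reside, and from the spleen, where immune responses to blood-borne and injected antigens develop. The mice had received 4 immunizations with phosphate-buffered saline (PBS), with ovalbumin alone (OVA alone), with ovalbumin and CpG oligonucleotides, which are ligands of Toll-like receptor 9, or with ovalbumin and Alum, an aluminium salt adjuvant. Libraries carrying CpG or Alum are called adjuvanted and the others unadjuvanted. Bone marrow contributed 12 IgG libraries, 3 per treatment. Spleen contributed 11, with 3 each for PBS, CpG and Alum and 2 for OVA alone. In the clone tables, bone marrow libraries held 2217 ± 1761 IgG sequences (SD, n = 12, range 655 to 6707) in 328 ± 178 clones. Spleen libraries held 5127 ± 4030 sequences (SD, n = 11, range 1203 to 13077) in 266 ± 134 clones. IgM clones were analysed in 10 of the libraries, 9 of bone marrow and 1 of spleen, with 82587 clones in all (1465 to 36876 per library). Whether libraries of the same number come from the same mouse is not given in the sources used here, so they were treated as separate samples.

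The first question was how IgG repertoires of bone marrow and spleen differ. Bone marrow IgG was spread over more clones: at equal numbers of sequences it held 106 ± 25.3 effective clones (SD, n = 12), against 42.8 ± 16.5 in the spleen (SD, n = 11). The 10 largest clones took 31.2% ± 9.54 of bone marrow sequences and 52.5% ± 14.2 of spleen sequences. The largest single clones of spleen libraries reached 31.4% of sequences in PBS 2 (95% Wilson interval 30.5 to 32.4), 28.5% in PBS 1 (27.4 to 29.7) and 23.0% in CpG 10 (22.3 to 23.7), and in the bone marrow none exceeded the 15.1% of PBS 2 (12.8 to 17.7). These intervals cover counting error only. The clone of spleen PBS 2 used IGHV14-2 and IGHJ2 with a CDR3 of 39 nucleotides and was also the largest clone of spleen PBS 3, at 24.8% (23.1 to 26.7). The largest clone of spleen PBS 1 used IGHV5-6 and IGHJ1, that of spleen CpG 10 used IGHV8-8 and IGHJ1, and that of bone marrow PBS 2 used IGHV1-80 and IGHJ3 with a CDR3 of only 15 nucleotides. None of these clones was private to its library. The same genes and CDR3 nucleotides occurred in 19 other libraries for the clone of spleen PBS 2. They occurred in 6 for spleen PBS 1, 4 for spleen CpG 10 and 12 for bone marrow PBS 2.

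Diversity was higher in bone marrow by 63.5 effective clones (two-sided permutation within treatments, p = 3.00e-05, adjusted p = 0.000750 over the 25 tests of the 5 values per library). In 10 of the 12 bone marrow libraries it lay above every spleen library. The share of the 10 largest clones fell by 21.3 percentage points from spleen to bone marrow (permutation p = 7.00e-05, adjusted p = 0.000875), with 9 of 12 bone marrow libraries below every spleen library. The smallest p these permutations can give is 1.00e-05. The 6 adjuvanted bone marrow libraries and spleen OVA alone 4 shared many identical clones and are not independent samples. Among the 6 bone marrow and 4 spleen libraries that remain with PBS or OVA alone once these are set aside, neither difference passed: it was 54.6 effective clones (exact permutation p = 0.0125, the smallest that 80 arrangements can give, adjusted p = 0.0521) and -19.1 percentage points for the largest clones (exact permutation p = 0.0250, adjusted p = 0.0849). Both were adjusted with the other tests of the family at their p-values for all libraries. These 10 libraries share clones too: 89.1% ± 7.96 of spleen PBS sequences (SD, n = 3) lay in clones found under another library number, against 40.0% (20.8% to 68.2%) in bone marrow PBS and 19.9% (10.7% to 32.1%) in bone marrow OVA alone (range, n = 3 each). In the remaining spleen library, OVA alone 6, 8.36% did, and it had 38.0 effective clones, below every bone marrow library.

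**Figure D1:**
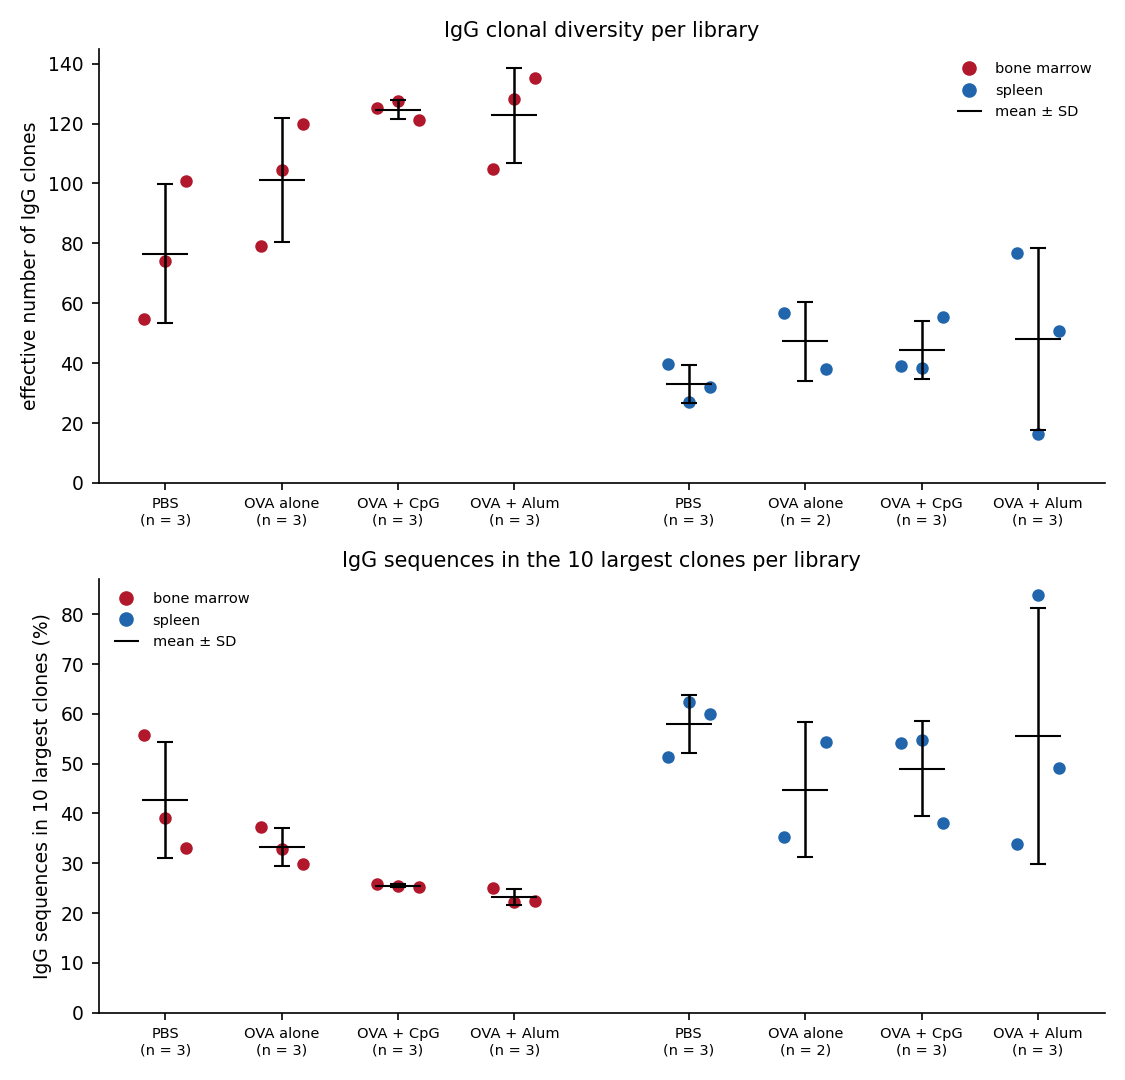
The upper panel shows the effective number of IgG clones per library and the lower panel the percent of IgG sequences in the 10 largest clones, both at 655 sequences per library, for each tissue and treatment. Points are libraries and bars are means with SD; diversity averaged 106 in bone marrow and 42.8 in the spleen.

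IgG mutation frequency was 0.844% ± 0.104 of V bases in bone marrow (SD, n = 12) and 0.719% ± 0.157 in the spleen (SD, n = 11). The difference of 0.124 percentage points did not pass (permutation p = 0.0349, adjusted p = 0.0970), and 8 of 12 bone marrow libraries lay above the median of all libraries. It was 0.160 and passed without spleen CpG 10 (permutation adjusted p = 0.0157), and it was 0.411 when every sequence was weighted alike (permutation adjusted p = 0.000375) and 0.173 with clones of another library number left out (permutation adjusted p = 0.0177). Among the unadjuvanted libraries other than spleen OVA alone 4 it was 0.0589 (exact permutation p = 0.450). Selection strength, the log2 excess of replacement over silent mutations in CDR1 and CDR2 relative to the framework regions, was 0.77 ± 0.24 in bone marrow and 0.42 ± 0.48 in the spleen. Its difference of 0.35 did not pass (permutation p = 0.0410, adjusted p = 0.103), except without spleen CpG 11 (0.44, permutation adjusted p = 0.0160) or without alleles that have an unusual framework 2 label (0.45, permutation adjusted p = 0.0356). CDR3 was 35.6 ± 0.892 nucleotides long in bone marrow and 36.4 ± 1.95 in the spleen (difference -0.818, permutation p = 0.188, adjusted p = 0.391). The difference was -0.330 without spleen CpG 10 (permutation adjusted p = 0.735) and -0.415 without CDR3 of over 100 nucleotides (permutation adjusted p = 0.608).

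Bone marrow clones used the IGHV1 family, the largest of the mouse, more often: it gave 57.5% ± 3.02 of bone marrow clones (SD, n = 12) and 51.7% ± 4.18 of spleen clones (SD, n = 11). The families nearest the D genes, IGHV2 and IGHV5, together gave 14.7% ± 2.11 of bone marrow clones and 17.8% ± 2.31 of spleen clones. Of these, IGHV5 stood at 10.4% ± 1.99 and 12.6% ± 1.49, and IGHV2 at 4.27% ± 0.621 and 5.21% ± 1.99. Among the joining genes, IGHJ4 was used by 27.9% ± 2.37 of bone marrow clones and 23.6% ± 4.85 of spleen clones, and IGHJ3 by 21.8% ± 1.63 and 25.3% ± 3.34. IGHJ1 (18.7% ± 2.12 and 19.1% ± 4.56) and IGHJ2 (31.6% ± 3.10 and 31.9% ± 3.22) did not differ detectably (permutation adjusted p = 0.756 for each).

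Of 18 families and fixed lists, 3 passed: IGHV1 (difference 5.80 percentage points, permutation adjusted p = 0.00738), IGHV5 (-2.20, permutation adjusted p = 0.0246) and the D-proximal list (-3.14, permutation adjusted p = 0.00738). IGHV2 by itself did not pass (permutation adjusted p = 0.409). Genes associated with B-1 cells (IGHV11-1, IGHV11-2 and IGHV12-3), some of which bind phosphatidylcholine, made up 0.203% ± 0.272 of bone marrow clones and 0.381% ± 0.496 of spleen clones (permutation adjusted p = 0.493). IGHV1-72, the canonical gene of the response to the hapten NP, made up 2.47% ± 0.909 and 1.99% ± 0.991 (permutation adjusted p = 0.466). Of 4 IGHJ genes, 2 passed: IGHJ3 (-3.53, permutation adjusted p = 0.0136) and IGHJ4 (4.35, permutation adjusted p = 0.0166). IGHV5 no longer passed when any of bone marrow PBS 1 (-2.12), PBS 2 (-1.91), PBS 3 (-1.97), spleen CpG 10 (-2.01), CpG 11 (-2.14) or CpG 12 (-2.07) was left out. With clones of another library number left out, IGHV1 (6.76, permutation adjusted p = 0.0236) and IGHJ4 (7.97, permutation adjusted p = 0.0136) passed, while IGHV5, the D-proximal list (both permutation adjusted p = 0.695) and IGHJ3 (permutation adjusted p = 0.0579) did not. That leaves 9 clones in bone marrow Alum 13 and 10 in spleen OVA alone 4. Without these 2 libraries, IGHV1 (5.87, permutation adjusted p = 0.0533) and IGHJ4 (4.46, permutation adjusted p = 0.0759) did not pass either. Counted by sequences, IGHJ3 did not pass either (permutation adjusted p = 0.508). Among the unadjuvanted libraries other than spleen OVA alone 4, 0 of 18 families and lists and 0 of 4 IGHJ genes passed the exact permutation test, with IGHV1 at 4.35 (adjusted p = 0.270), the D-proximal list at -3.46 (adjusted p = 0.225), IGHJ3 at -4.78 and IGHJ4 at 5.12 (adjusted p = 0.125 for both). The smallest p this exact permutation can give is 0.0125 (80 arrangements). A single item at that p could not pass over 18 or 4 tests, so these counts of 0 do not argue against the differences.

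**Figure D2:**
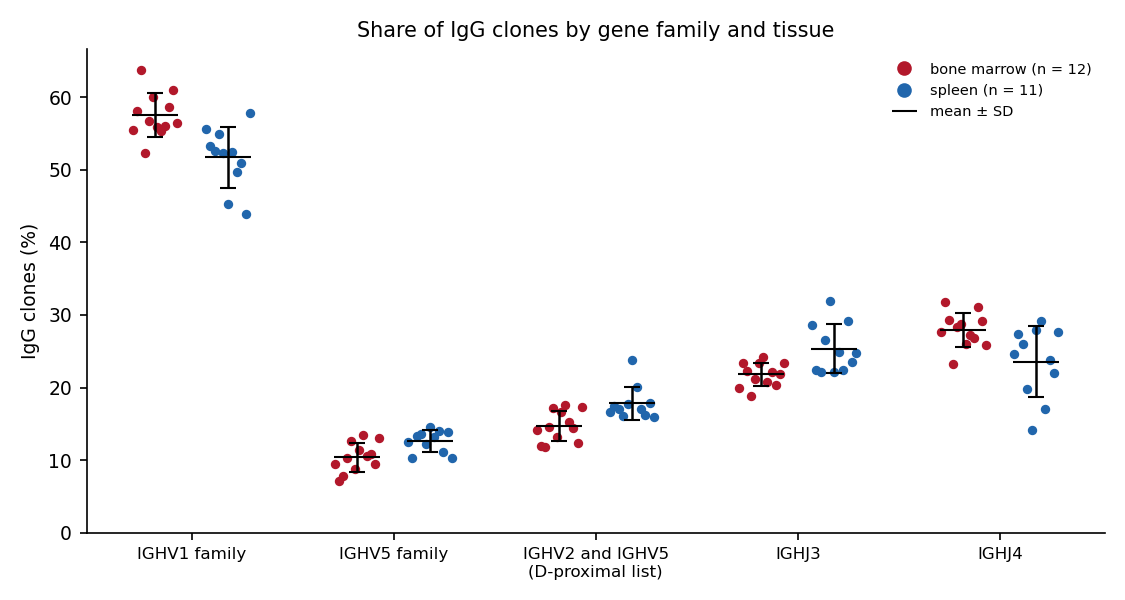
The percent of IgG clones that use the IGHV1 family, the IGHV5 family, the IGHV2 and IGHV5 families together, IGHJ3 or IGHJ4 is plotted for the libraries of bone marrow (n = 12) and spleen (n = 11). Points are libraries and bars are means with SD; the IGHV1 family averaged 57.5% in bone marrow and 51.7% in the spleen.

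At the level of single genes, IGHV1-26 (5.41% ± 0.875 of bone marrow clones and 5.0% ± 2.16 of spleen clones) and IGHV3-6 (5.14% ± 1.33 and 4.87% ± 3.38) were used most. The other genes with the largest shares were IGHV6-3, IGHV1-80, IGHV5-17, IGHV9-3, IGHV1-55, IGHV1-53, IGHV1-18 and IGHV4-1, which took on average between 2.41% and 3.25% of clones; IGHV1-18 stayed below the filter on counts. No tested gene passed between the tissues in edgeR (0 of 10, 2 at an unadjusted p under 0.05, 0 in DESeq2). Those 2 were IGHV1-55, with 3.10% ± 1.13 of bone marrow clones and 2.21% ± 1.10 of spleen clones (log2 difference 0.59, SE 0.28, edgeR adjusted p = 0.179), and IGHV5-17, with 2.15% ± 0.787 and 3.55% ± 1.89 (log2 difference -0.56, SE 0.26, edgeR adjusted p = 0.179). IGHV6-3 had a log2 difference of -0.41 (SE 0.21), IGHV9-3 of 0.32 and IGHV2-2 of -0.50, and IGHV1-80, IGHV1-53 and IGHV4-1 lay between -0.07 and -0.05, with signs that turned when single libraries were left out. IGHV9-3 turned to -0.69 when clones found under another library number and the filter on low counts were both left out, and IGHV2-2 to 0.14 without the adjuvanted bone marrow libraries and spleen OVA alone 4. The sign of IGHV5-17 turned without spleen OVA alone 6 (0.0137). Adjusted over the list alone, 0 of the 4 tested IGHV1 genes (lowest edgeR adjusted p = 0.160) and 0 of the 2 tested D-proximal genes (lowest edgeR adjusted p = 0.0780) passed. With sequences counted instead of clones, 78 genes were tested in edgeR and 15 passed. IGHV1-69, chosen after its values were seen, passed in edgeR without bone marrow PBS 2 (log2 difference 1.27, adjusted p = 0.0196), bone marrow OVA alone 6 (1.32, adjusted p = 0.0385), spleen OVA alone 4 (1.38, adjusted p = 0.0227) or spleen CpG 11 (adjusted p = 0.00543). No fold is given for the last, since the spleen CpG libraries then hold 0 clones of IGHV1-69.

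The second question was whether an adjuvant alters the IgG repertoire of the bone marrow. Adjuvanted bone marrow carried longer CDR3 loops, the most variable part of the antibody, with 36.3 ± 0.170 nucleotides (SD, n = 6) against 34.9 ± 0.739 in unadjuvanted bone marrow (SD, n = 6). It also held more effective clones, 124 ± 10.3 against 88.9 ± 23.9, and its 10 largest clones took 24.4% ± 1.62 of sequences against 38.0% ± 9.29. By treatment, the effective clones were 76.5 ± 23.3 with PBS, 101 ± 20.7 with OVA alone, 125 ± 3.08 with CpG and 123 ± 16.0 with Alum (SD, n = 3 each). CDR3 length was 34.6 ± 0.920, 35.1 ± 0.584, 36.2 ± 0.178 and 36.3 ± 0.195 nucleotides in the same order, and the 10 largest clones took 42.7% ± 11.7, 33.3% ± 3.82, 25.5% ± 0.332 and 23.2% ± 1.54. The 6 adjuvanted bone marrow libraries shared 47.4% to 83.8% of the clones of the smaller library of each pair and are not independent samples. The p-values of all adjuvant comparisons in bone marrow are therefore too small to an unknown degree. The summed numbers in the sequence names also separated these libraries, at 504295 to 728350 against 30667 to 343317 in unadjuvanted bone marrow. At least 8.63% of their sequence names carried an identifier, against at most 5.82%. Whether such a difference between libraries explains the higher diversity or the lower share of the largest clones was not tested.

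The difference in CDR3 length was 1.40 nucleotides (two-sided exact permutation p = 0.00216, the smallest this design can give, adjusted p = 0.0135), with 6 of 6 adjuvanted libraries above all others. It was 0.833 with the median per library (exact permutation adjusted p = 0.720) and 1.04 with clones of another library number left out (exact permutation p = 0.225, adjusted p = 0.433), and neither passed. With those clones and Alum 13, where 9 clones remain, left out, it was 1.66 and did not pass (exact permutation p = 0.0195, adjusted p = 0.0755). The share of the 10 largest clones fell by 13.6 percentage points (exact permutation p = 0.00216, adjusted p = 0.0135), with 6 of 6 adjuvanted libraries below all others. Diversity was higher by 34.8 effective clones (exact permutation p = 0.00433, adjusted p = 0.0216), with 5 of 6 above all others. Diversity no longer passed without CpG 11 (34.1), Alum 14 (33.9) or Alum 15 (32.5), each with an exact permutation adjusted p of 0.0541, nor when distinct clones were counted (20.5, exact permutation adjusted p = 0.290). Across the 4 treatments, the share of the largest clones differed (F = 6.05, permutation p = 0.00998, adjusted p = 0.0416). That call was lost without any 1 of OVA alone 4, 5 or 6 (F = 5.61, 5.28 and 5.78), CpG 10, 11 or 12 (F = 5.07, 5.03 and 5.0), or Alum 13, 14 or 15 (F = 5.09, 4.66 and 4.69). CDR3 length (F = 6.63, permutation p = 0.0211, adjusted p = 0.0755) did not pass across the 4 treatments, but did so without PBS 3 (F = 10.3, permutation adjusted p = 0.0232), without OVA alone 4 (F = 6.63, permutation adjusted p = 0.0398) or over sequences (F = 7.68, permutation adjusted p = 0.0176). Diversity did not pass across the 4 treatments (F = 4.93, permutation p = 0.0272, adjusted p = 0.0849), but the inverse Simpson index did (F = 26.7, permutation adjusted p = 0.00192).

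Mutation frequency was 0.873% ± 0.0679 in adjuvanted and 0.814% ± 0.131 in unadjuvanted bone marrow (difference 0.0590, exact permutation p = 0.338, adjusted p = 0.563), and the 4 treatments did not differ detectably (F = 0.525, permutation adjusted p = 0.863). Selection strength was 0.64 ± 0.19 and 0.89 ± 0.24 on the log2 scale (difference -0.25, exact permutation p = 0.0714, adjusted p = 0.162), with F = 1.96 across the 4 treatments (permutation adjusted p = 0.398). The lower selection strength passed without PBS 2 (-0.33, exact permutation adjusted p = 0.0356) or without alleles with an unusual framework 2 label (-0.37, exact permutation adjusted p = 0.0271). IGHV1-53 had the largest fitted difference, with 3.14% ± 1.43 of clones with PBS, 3.44% ± 1.33 with OVA alone, 1.55% ± 0.940 with CpG and 1.69% ± 0.462 with Alum (SD, n = 3 each). Its log2 difference was -0.98 (SE 0.34, edgeR adjusted p = 0.0623). No gene passed in edgeR (0 of 10, 1 at an unadjusted p under 0.05, 0 in DESeq2). Adjusted over the list alone, 1 of 4 tested IGHV1 genes, IGHV1-53, passed (edgeR adjusted p = 0.0249), and it passed over all genes without CpG 11 (log2 difference -1.27, edgeR adjusted p = 0.0113). The adjustment over the list was run only with all libraries, so how far that call rests on single libraries was not tested. Other genes passed edgeR under other counting, each chosen after its values were seen: IGHV7-3, IGHV5-2 and IGHV5-15 without the filter on low counts, and IGHV9-1, IGHV7-3, IGHV5-2 and IGHV15-2 with sequences counted. CpG against Alum and OVA alone against PBS gave no called gene in edgeR (0 of 10 each, 0 at an unadjusted p under 0.05, 0 in DESeq2), and again the CpG and Alum libraries share clones.

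**Figure D3:**
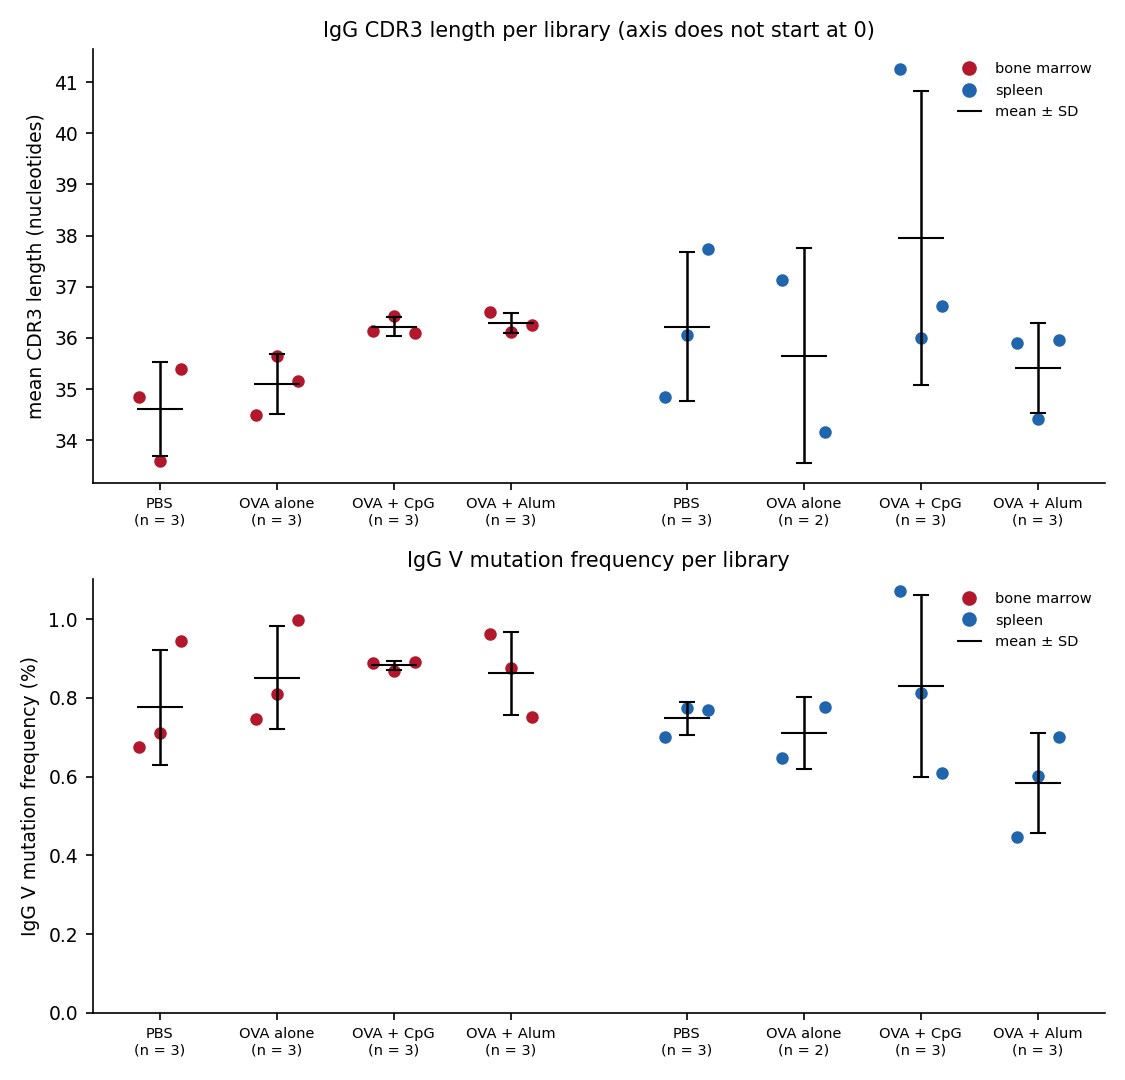
The upper panel shows the mean IgG CDR3 length in nucleotides per library and the lower panel the mean IgG mutation frequency in percent of V bases, for each tissue and treatment. Points are libraries and bars are means with SD; CDR3 averaged 36.3 nucleotides in adjuvanted and 34.9 in unadjuvanted bone marrow, on an axis that does not start at 0.

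In the spleen, the same question was asked of 6 adjuvanted and 5 unadjuvanted libraries. None of the 5 values passed for adjuvant or across the 4 treatments (10 permutation tests). Effective clones were 33 ± 6.38 with PBS, 47.3 ± 13.1 with OVA alone (n = 2), 44.3 ± 9.69 with CpG and 48.0 ± 30.4 with Alum (SD, n = 3 each where not stated). Adjuvanted spleen held 46.1 ± 20.3 effective clones against 38.7 ± 11.2 (difference 7.44, exact permutation p = 0.50), and its 10 largest clones took 52.3% ± 17.7 against 52.7% ± 10.7 of sequences (exact permutation p = 0.968). CDR3 measured 36.7 ± 2.35 nucleotides in adjuvanted and 36.0 ± 1.5 in unadjuvanted spleen (difference 0.699, exact permutation p = 0.654), and the sign turned without CpG 10 (-0.215). Mutation frequency was 0.707% ± 0.215 and 0.734% ± 0.0578 (exact permutation p = 0.794), and selection strength was 0.46 ± 0.48 and 0.36 ± 0.55 (exact permutation p = 0.747). Near 0, other signs turned as well: mutation frequency without Alum 13 (0.0254), selection strength without PBS 3 (-0.0926) or CpG 11 (-0.0685), and the largest clones without PBS 2 (2.06), PBS 3 (1.45), OVA alone 6 (0.0282), CpG 12 (2.48), Alum 13 (3.32) or Alum 15 (0.241). The smallest p that 6 against 5 libraries can give is 0.00216.

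The adjuvant effects of bone marrow were not shown to differ from those of spleen. The effect in bone marrow minus that in spleen was 27.4 effective clones (permutation p = 0.124), -13.2 percentage points for the largest clones (permutation p = 0.209), 0.702 nucleotides for CDR3 (permutation p = 0.645), 0.0856 for mutation frequency (permutation p = 0.472) and -0.35 for selection strength (permutation p = 0.297), with a lowest adjusted p of 0.495 over these 5 tests. With 1 library left out, these values ranged from 20.6 to 33.6 for effective clones, from -16.9 to -6.91 for the largest clones, from 0.245 to 1.61 for CDR3 (highest without spleen CpG 10). They ranged from 0.0336 (without spleen Alum 13) to 0.158 (without spleen CpG 10) for mutation frequency and from -0.51 to -0.16 for selection strength. None passed. These tests were not planned, and the adjuvanted bone marrow libraries that enter them share clones.

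Among single genes, IGHV5-17 made up 5.75% ± 1.18 of spleen clones with CpG and 2.79% ± 0.382 with Alum, and IGHV2-2 3.90% ± 1.37 and 1.33% ± 1.37 (SD, n = 3 each). Both genes belong to the D-proximal families. Over all tested genes neither passed between CpG and Alum (log2 differences 0.94, SE 0.41, and 1.19, SE 0.50; edgeR adjusted p = 0.145 for each), and the count was 0 of 10 in edgeR, 2 at an unadjusted p under 0.05 and 0 in DESeq2. Adjusted over the list alone, 2 of 2 tested D-proximal genes passed (edgeR adjusted p = 0.0289). This adjustment was run only with all libraries, so how far it rests on single libraries was not tested. The spread behind it is estimated over all 8 groups. The adjuvanted bone marrow libraries, which share clones, enter that estimate. The edgeR p-values in the spleen may therefore be too small to an unknown degree. Without spleen CpG 11, IGHV5-17 (log2 difference 1.42, edgeR adjusted p = 0.0354) and IGHV1-69 (edgeR adjusted p = 0.0326, chosen after its values were seen) passed. IGHV1-69 then had 0 clones in both CpG libraries and 6, 5 and 7 in the Alum libraries, so no fold is given. Counting sequences gave 8 called genes, and leaving out the filter on low counts gave 1, IGHV14-4, also chosen after its values were seen (0, 0 and 1 clones with CpG and 6, 2 and 14 with Alum, edgeR adjusted p = 0.0222). Adjuvanted against unadjuvanted spleen gave 0 of 10 in edgeR (0 at an unadjusted p under 0.05, 0 in DESeq2). With sequences counted, IGHV14-1, IGHV1-34 and IGHV1-66, chosen after their values were seen, passed there in edgeR. OVA alone against PBS gave 0 of 10 (1 at an unadjusted p under 0.05, 0 in DESeq2). The gene at that level was IGHV4-1, with 3.86% ± 4.59 of clones in the 2 OVA alone libraries and 1.29% ± 0.635 with PBS (log2 difference 1.55, SE 0.73, edgeR adjusted p = 0.413). Its log2 difference turned to -1.28 without OVA alone 6, and with sequences counted IGHV14-2, IGHV6-6 and IGHV1-15, chosen after their values were seen, passed for OVA alone against PBS.

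IgM and IgG of the same library were compared to set class-switched clones against the unswitched background of the same tissue. IgG clones carried more mutations, with 0.821% ± 0.134 of V bases against 0.146% ± 0.0658 in IgM (SD, n = 10 pairs). The IgG repertoire was less diverse, with 90.8 ± 35.1 effective clones against 328 ± 215 at equal numbers of sequences. Among IGHV genes, IGHV4-1 took 2.76% ± 1.70 of IgG and 1.27% ± 0.305 of IgM clones, while IGHV5-4 took 1.21% ± 0.692 and 2.81% ± 0.393 and IGHV8-8 1.12% ± 0.600 and 2.59% ± 1.44. CDR3 was 35.2 ± 0.911 nucleotides long in IgG and 35.8 ± 0.456 in IgM.

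Mutation frequency was higher in IgG in 10 of 10 libraries, by 0.675 percentage points (two-sided exact permutation of signs, p = 0.00195, the smallest possible, adjusted p = 0.00586). Diversity fell by 237 effective clones from IgM to IgG and was higher in IgG in 1 of 10 libraries (exact permutation p = 0.00391, adjusted p = 0.00586). The CDR3 difference of -0.546 nucleotides did not pass (exact permutation p = 0.119), with IgG longer in 3 of 10 libraries. It was -1.07 and passed without the adjuvanted bone marrow libraries (exact permutation adjusted p = 0.0156; IgG longer in 0 of 7), and it was -0.741 and passed without bone marrow Alum 13 (exact permutation adjusted p = 0.0430). In edgeR, with the library as a block, 9 of 36 genes passed (12 at an unadjusted p under 0.05, 11 called in DESeq2). Higher in IgG were IGHV4-1 (log2 difference 1.17, SE 0.29, edgeR adjusted p = 0.00160, 7 of 10 libraries), IGHV1-74 (0.85, 8 of 10), IGHV1-39 (0.80, 9 of 10) and IGHV9-3 (0.61, 7 of 10). Lower in IgG were IGHV5-4 (-1.22, SE 0.29, edgeR adjusted p = 0.000960), IGHV8-8 (-1.04, SE 0.30, edgeR adjusted p = 0.00905), IGHV10-1 (-1.21), IGHV8-12 (-0.88) and IGHV6-3 (-0.59), with IgG above IgM in 0, 0, 2, 1 and 1 of 10 libraries in that order. IGHV4-1, IGHV5-4 and IGHV8-8 passed with any 1 library left out, and each of the others lost its call without at least 1 library. The count of called genes was 15 without bone marrow PBS 3, 3 without CpG 10, 4 without Alum 13 and 3 without Alum 14 of the bone marrow, 5 with sequences counted and 22 without the filter on low counts. The adjuvanted bone marrow libraries share clones in this comparison too, and without them IGHV5-4 (-0.95, edgeR adjusted p = 0.0218) and IGHV8-8 (-1.31, edgeR adjusted p = 0.000772) were the 2 genes that passed.

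**Figure D4:**
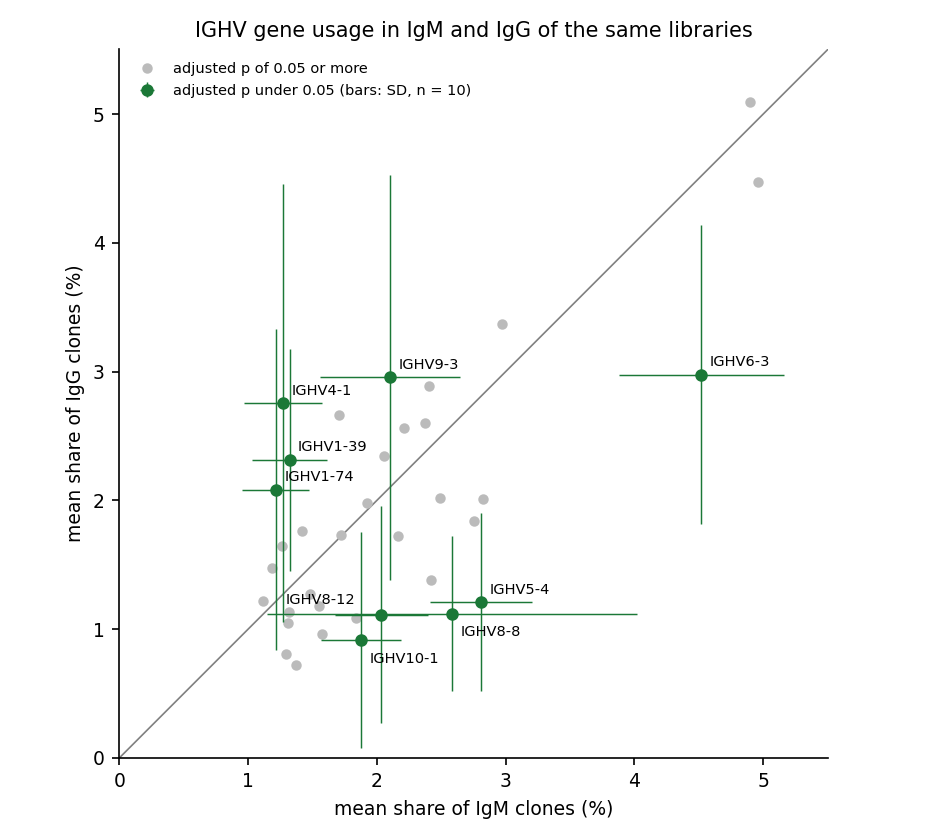
The mean share of IgG clones (vertical axis, percent) is plotted against the mean share of IgM clones (horizontal axis, percent) for the 36 tested IGHV genes over 10 libraries, with a line of equal shares. Named points are the 9 genes that passed; IGHV5-4 lies below the line at 1.21% of IgG and 2.81% of IgM clones, and IGHV4-1 above it at 2.76% and 1.27%.

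The overlap of clones was counted to ask how far animals and tissues share the same IgG, where clones match in IGHV gene, IGHJ gene and CDR3 nucleotides. Pairs of adjuvanted bone marrow libraries shared 64.3% ± 10.7 of the clones of the smaller library (SD, 15 pairs, 114 to 309 clones), pairs of unadjuvanted bone marrow libraries 5.69% ± 10.4 (15 pairs), and pairs of spleen libraries 3.65% ± 8.42 (55 pairs). Sharing was at a similar level within CpG (60.5% ± 11.5, 3 pairs), within Alum (69.3% ± 6.87, 3 pairs) and between CpG and Alum (63.9% ± 11.9, 9 pairs). Spleen OVA alone 4 shared 88.9% of its clones, 144 in number, with bone marrow Alum 15 and 6.17% with the bone marrow library of its own number. The 3 spleen PBS libraries shared 32.5% ± 19.8 with each other (16.7% to 54.8%), and bone marrow PBS 1 and 2 shared 41.9%. The largest clones followed the same lines: an IGHV3-6 and IGHJ1 clone with a CDR3 of 42 nucleotides was the largest of bone marrow CpG 11, CpG 12 and Alum 14 (3.5%, 3.57% and 3.14% of sequences), and an IGHV6-3 and IGHJ3 clone of 33 nucleotides led both bone marrow Alum 15 (3.01%, 95% Wilson interval 2.53 to 3.58) and spleen OVA alone 4 (4.55%, 3.77 to 5.48).

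Bone marrow and spleen of the same number shared 5.81% ± 3.73 of clones (SD, 11 pairs, 3 to 26 clones). That was 12.8 clones on average, against 11.7 for pairs of different numbers within a treatment (one-sided exact permutation of the numbers within treatments, p = 0.362 over 1296 arrangements), and the sign of the difference turned without bone marrow PBS 1 (-0.10) or spleen PBS 1 (-0.35) or PBS 2 (-0.55). Pairs of the same number shared 7.22% ± 4.86 when unadjuvanted (SD, 5 pairs) and 4.63% ± 2.28 when adjuvanted (SD, 6 pairs). Bone marrow libraries within CpG and within Alum share most clones, so own and other numbers are hard to tell apart there. The test therefore cannot show that sharing within a number is absent. By amino acids, 865 clonotypes occurred under at least 2 numbers, 848 of them with an identical nucleotide sequence under at least 2 numbers. Pairs of library numbers within a treatment shared 125 clonotypes on average and pairs between treatments 61.9 (one-sided permutation p = 0.000260). That permutation takes the 12 numbers as independent samples, which they are not. Adjuvanted bone marrow libraries shared clones at a similar level within and between CpG and Alum, so the p-value cannot show that clonotypes follow the treatment. With identical nucleotide sequences left out, 17 clonotypes were left, with 0.583 per pair within and 0.259 per pair between treatments (one-sided permutation p = 0.0678). The ratio of the means did not fall, and so few clonotypes cannot show a difference in numbers like the 63.5 of all clonotypes. Present under all 12 numbers were IGHV1-80 with IGHJ3 and the CDR3 ARGAY, in 5 nucleotide versions, IGHV14-2 with IGHJ2 and ASYYDYDGYYFDY, and IGHV5-9.1 with IGHJ4 and TRVLEAMDY. IGHV9-2 with IGHJ2 and ARYYYSNYYFDY was present under 11, and IGHV8-5 with IGHJ3 and AQMRGFAY, IGHV2-2 with IGHJ4 and ARKTTVVPYYAMDY, and IGHV6-3 with IGHJ1 and TGHSDGYSYWYFDV under 10.

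**Figure D5:**
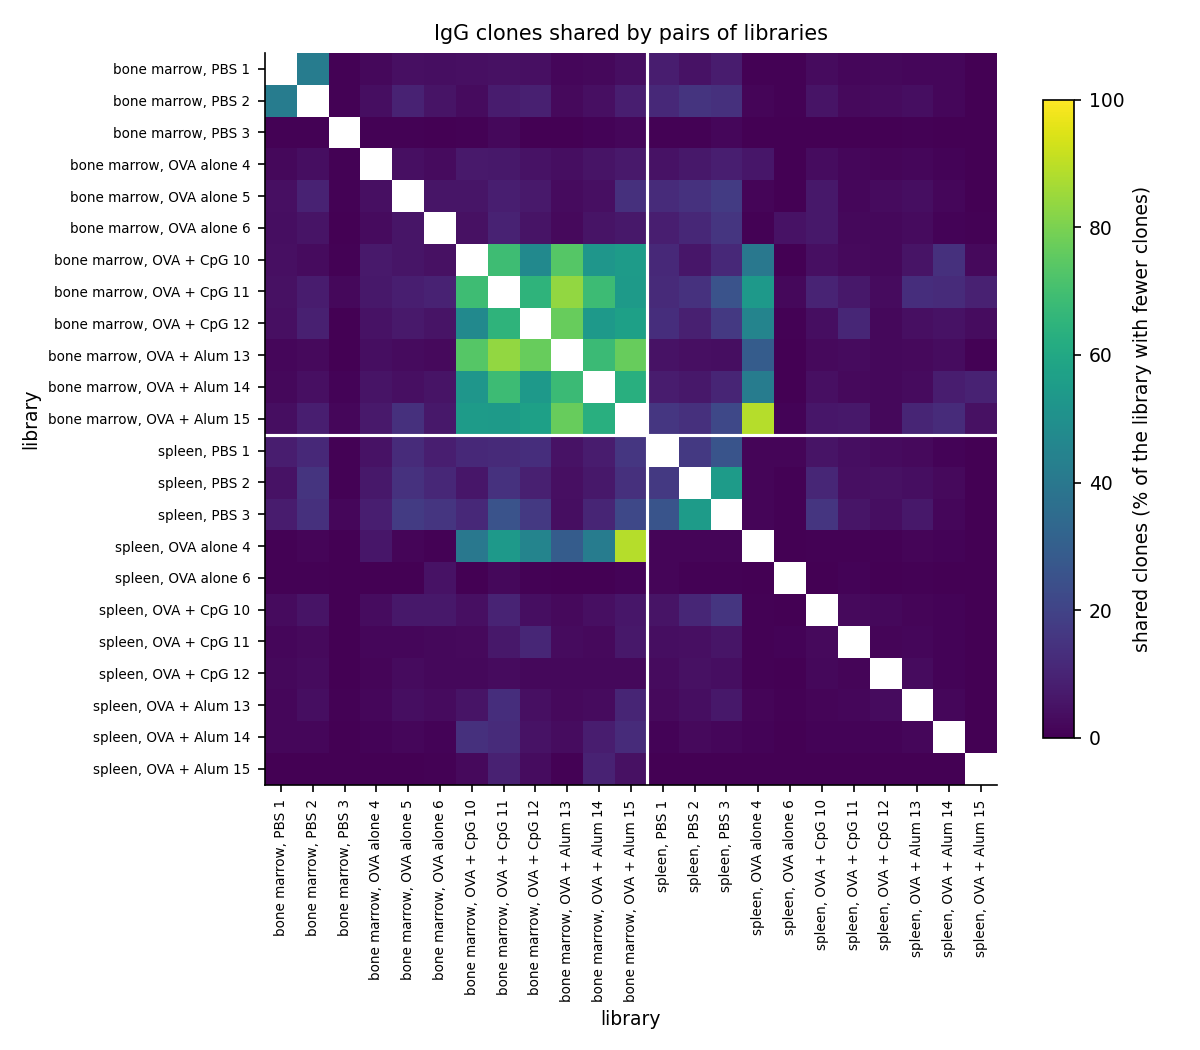
Each cell gives the IgG clones shared by a pair of libraries as percent of the library with fewer clones, with bone marrow and spleen libraries ordered by treatment on both axes. The block of the 6 adjuvanted bone marrow libraries lies between 47.4% and 83.8%, and spleen OVA alone 4 reaches 88.9% with bone marrow Alum 15.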

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

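The tests for single libraries that stand apart within an arm were chosen only after the results were seen. They took 5 values per library in 4 sets of libraries, which made 20 sets, and chance alone singles out a library in about 1 in 20.

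Bone marrow PBS 1 had 55.7% of its IgG sequences in its 10 largest clones, and the gap to the nearest of the 6 unadjuvanted bone marrow libraries was 0.637 of their whole range. Spleen CpG 10 had a mean IgG CDR3 length of 41.3 nucleotides, with a gap of 0.677 of the range of the 6 adjuvanted spleen libraries, and it held 2 clones with a CDR3 of over 100 nucleotides.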

How the results depend on the processing

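Tests with substitutions over all V bases, without alleles with an unusual framework 2 label, without CDR3 over 100 nucleotides, without clones found under another library number (also without the libraries then left with few clones), and without the adjuvanted bone marrow libraries (for tissues also without spleen OVA alone 4) were chosen only after the results were seen, as was every test of the adjuvant effect between tissues, while the others were planned. Of 1292 values with 1 library left out, 1184 kept their direction and their side of the threshold, 47 lost a call, 8 gained one, 10 counts moved and 43 turned sign. Of 380 other values (253 planned, 127 added), 288 kept both, 43 lost a call, 10 gained one, 21 moved and 18 turned sign. Selection strength with CDR3 was not run, because the mutation tables end at framework 3, and diversity, the largest clones and selection strength were not run without clones of other numbers. Where not stated otherwise, the cause was not tested. Depth limits the IGHV tests: 10 genes passed the filter on clone numbers.

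Over sequences instead of clones, the tissue difference in mutation frequency was 0.411 and passed, that for adjuvant in the spleen turned to 0.0558, and CDR3 length over 4 treatments in bone marrow passed (F = 7.68). Counting sequences called 15 IGHV genes between tissues, 4 for adjuvant in bone marrow, 3 for adjuvant in the spleen, 8 for CpG against Alum in the spleen, 3 for OVA alone against PBS in the spleen and 5 between IgM and IgG. It turned IGHV1-80 to 0.13 and IGHV1-53 to 0.48 between tissues, IGHV9-3 to -0.39 between isotypes and the B-1 list to 0.321, and it left 1 IGHJ gene called. With medians, the adjuvant effect in bone marrow was -0.0171 for mutation frequency and 0.833 for CDR3 length, which lost its call. The inverse Simpson index called diversity over 4 treatments in bone marrow (F = 26.7), and distinct clones did not call it for adjuvant (20.5). Without the filter on low counts, where more genes were tested, the IGHV counts were 3 for adjuvant in bone marrow, 1 for CpG against Alum in the spleen and 22 between IgM and IgG.

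Without clones found under another library number, mutation frequency between tissues passed (0.173), CDR3 length for adjuvant in bone marrow did not (1.04), 1 IGHJ gene and 1 family were called, and IGHJ1 turned to 0.286. With the 2 libraries that then keep fewer than 20 clones left out too, mutation frequency was 0.185 and passed, CDR3 length was 1.66 and did not, 0 IGHJ genes and 0 families were called, and IGHJ2 turned to 1.12. With the shared clones and the filter on low counts left out, IGHV1-26, IGHV3-6 and IGHV9-3 turned to -0.36, -0.24 and -0.69, while leaving out the filter alone gave 0.10, 0.16 and 0.32. Without the adjuvanted bone marrow libraries and spleen OVA alone 4, where only unadjuvanted libraries of both tissues remain to be permuted, the tissue differences in diversity (54.6) and the largest clones (-19.1) lost their calls with fewer samples, 0 IGHJ genes and 0 families were called, and IGHV1-80 (0.30), IGHV1-53 (1.17), IGHV2-2 (0.14), IGHJ1 (0.317) and the B-1 list (0.197) turned sign. By itself, no family, list or IGHJ gene could pass there at 0.0125, the smallest p of that exact permutation. Without the adjuvanted bone marrow libraries, 2 IGHV genes were called between IgM and IgG, and the CDR3 difference passed (-1.07). Without alleles with an unusual framework 2 label, selection strength passed between tissues (0.45) and for adjuvant in bone marrow (-0.37). Clonotypes under several numbers were 443 with clones of at least 2 sequences and 17 without identical nucleotides, where with so few left the difference in numbers was 0.324 (0.583 within and 0.259 between treatments).

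Library numbers were not shown to pair the samples. The deviations of the same number in both tissues correlated between -0.346 and 0.429, and 4 of 11 correlated best with their own number. These were PBS 1, PBS 2, PBS 3 and OVA alone 6. The rest were OVA alone 4, whose spleen library shares clones with other numbers, and the adjuvanted numbers, whose bone marrow libraries do. With 2 spleen libraries of OVA alone, own and other correlations mirror each other by construction. The check therefore cannot show that pairing is absent. With the number as a block, diversity (63.7, exact permutation adjusted p = 0.0122) and the largest clones (-21.4, exact permutation adjusted p = 0.0216) passed between tissues, 0 IGHJ genes and 1 list (D-proximal, -3.37, exact permutation adjusted p = 0.0352) were called, IGHV1 (5.87) and IGHV5 (-2.40; both exact permutation adjusted p = 0.0586) and IGHJ3 (-3.48) and IGHJ4 (4.31; both exact permutation adjusted p = 0.0566) were not, and IGHV1-80 (0.0125) and IGHV4-1 (0.15) turned sign between tissues.

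With 1 library left out, mutation frequency ranged from 0.0973 to 0.160 between tissues (passing without spleen CpG 10) and from -0.0993 to 0.0254 for adjuvant in the spleen (positive without Alum 13). CDR3 length ranged from -1.04 to -0.330 between tissues, from F = 5.10 to 10.3 over 4 treatments in bone marrow and from -0.215 to 1.16 for adjuvant in the spleen (negative without CpG 10), and the adjuvant effect in bone marrow minus that in spleen from 0.245 to 1.61 (highest without spleen CpG 10). That effect ranged from 0.0336 to 0.158 for mutation frequency, from 20.6 to 33.6 for diversity, from -16.9 to -6.91 for the largest clones and from -0.51 to -0.16 for selection strength. Diversity for adjuvant in bone marrow ranged from 28.0 to 41.1. The largest clones ranged from F = 4.66 to 13.1 over 4 treatments in bone marrow and from -6.71 to 3.32 for adjuvant in the spleen. Selection strength ranged from 0.27 to 0.44 between tissues, from -0.33 to -0.19 for adjuvant in bone marrow and from -0.0926 to 0.26 for adjuvant in the spleen. The IGHV counts ranged from 0 to 1 between tissues and for adjuvant in bone marrow, from 0 to 2 for CpG against Alum in the spleen and from 3 to 15 between IgM and IgG. Between tissues, IGHV1-80 ranged from -0.18 to 0.31, IGHV5-17 from -0.70 to 0.0137, IGHV1-53 from -0.25 to 0.14, IGHV4-1 from -0.22 to 0.64, IGHJ1 from -1.06 to 0.512 and IGHJ2 from -1.03 to 0.158. IGHV4-1 ranged from -1.28 to 1.90 for OVA alone against PBS in the spleen, where leaving out 1 of 2 libraries assumes that the lone one varies like other groups. CDR3 length between IgG and IgM ranged from -0.741 to -0.404, and clones shared by the tissues of 1 number, relative to other numbers, from -0.55 to 3.5.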

Other observations

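The tests of mutation placement, mutated bases and junctions, of IgM mutation tables, the tests of carried material and of convergent recombination among the adjuvanted bone marrow libraries, the test of shared identifiers and the counts over other splits of the libraries were chosen only after the results were seen.

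IgG mutations lay in CDR1 and CDR2 more often in bone marrow, where these loops held 27.4% ± 2.53 of distinct mutations (SD, n = 12), than in the spleen with 23.0% ± 1.22 (SD, n = 11). In bone marrow, 58.4% ± 1.68 of distinct mutations were at C, the base that the mutator enzyme AID deaminates, or G, its partner on the other strand, against 54.7% ± 1.27 in the spleen. Both differences passed a two-sided permutation test within treatments, at 4.42 percentage points (p = 3.00e-05, adjusted p = 0.000540) and 3.62 (p = 8.00e-05, adjusted p = 0.000720) in a family of 18 tests. Of the 12 bone marrow libraries, 9 lay above every spleen library for CDR1 and CDR2 and 11 for C or G bases. The adjuvanted bone marrow libraries share clones, and neither passed among the unadjuvanted libraries other than spleen OVA alone 4 (5.26, exact permutation adjusted p = 0.0616, and 2.57, exact permutation adjusted p = 0.150). The smallest p of that exact permutation, 0.0125, could not pass in this family of 18 tests. This loss therefore does not argue against either difference.

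Transitions made up 61.4% ± 4.39 of distinct mutations in bone marrow and 66.4% ± 4.22 in the spleen (permutation adjusted p = 0.0616), and out of frame sequences 1.44% ± 0.416 and 1.98% ± 0.630 (permutation adjusted p = 0.0848). Unmutated clones were about as common in both tissues, at 30.5% ± 4.13 and 31.2% ± 5.95 (permutation adjusted p = 0.766). Adjuvanted bone marrow clones had 7.90 ± 0.117 N nucleotides at their junctions against 7.30 ± 0.517 in unadjuvanted bone marrow (n = 6 each, exact permutation p = 0.0108, adjusted p = 0.0616). In the IgM mutation tables, mutated sequences carried 1.89 ± 0.185 substitutions in adjuvanted and 2.31 ± 0.316 in unadjuvanted spleen (n = 6 and 5, exact permutation p = 0.0303, adjusted p = 0.121), and 2.67 ± 0.224 and 2.65 ± 0.703 in bone marrow (n = 6 each, exact permutation p = 0.965). CDR1 and CDR2 held 25.8% ± 0.568 of IgM mutations in adjuvanted and 27.9% ± 3.92 in unadjuvanted bone marrow, and 25.6% ± 3.52 and 26.3% ± 2.12 in the spleen. IgM clones overlapped too: bone marrow PBS 1 and 2 shared 386 (13.5% of the smaller library), and bone marrow CpG 10, Alum 13 and Alum 14 shared 12.3% to 16.5% with each other.

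Identical IgG clones joined libraries of different numbers, above all the 6 adjuvanted bone marrow libraries, where a median of 61.9% of the V substitutions of a shared clone recurred in its copy in the other library, against 2.98% between different clones of the same IGHV gene. The lowest excess over 15 pairs was 54.6 percentage points, which argues against independent recombination, and substitutions at the last base of codons, mostly silent, recurred 1.03 times as often as the others, which argues against selection of the same mutations by antigen. The 6 pairs of spleen OVA alone 4 with these libraries had 23.1% to 92.3% against at most 1.61%, and the 31 other pairs that shared at least 10% of clones had a median of 12.3% (5.30% to 85.2%) against 1.18%. Over all 52 pairs it was 34.0% against 1.47%. Of 8231 sequences with an identifier in shared clones, 83 (1.01%) had the same identifier and clone in the other library, in 19 pairs. Within adjuvanted bone marrow these were 58 of 2359, in 9 of 15 pairs. How often identifier and clone match by chance was not tested. Clones found under another number differed from the rest by -1.11 N nucleotides over 18 libraries (SD 1.04) and by -1.32 over the 13 outside adjuvanted bone marrow (SD 0.881), as convergent recombination would give, so that for these 31 pairs it and carried material cannot be told apart. As a hypothesis, a candidate explanation for the recurring substitutions within adjuvanted bone marrow is carried material; the step at which material would have been carried was not tested.

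Longer CDR3 in adjuvanted bone marrow went from 1.40 to 1.04 nucleotides without clones found under another library number, and to 1.66 without Alum 13 as well, which then kept 9 clones, so the few clones left cannot tell whether shared clones carry the difference. Outside adjuvanted bone marrow, CDR3 length was related to the logarithm of the summed numbers in the sequence names, which may reflect sequencing depth. CDR3 over 100 nucleotides were left out of this relation. Length then increased with these numbers (Spearman rho 0.485, permutation p = 0.0513, adjusted p = 0.154 over 3 relations). Pearson r was 0.351 (permutation p = 0.171), and 0.373 without the 2 farthest of 17 libraries. These values do not hold for the mean length with every CDR3 kept, for which no value is given here. A difference in depth is therefore a possible explanation that was not excluded, and an effect of the adjuvant itself stays open.

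If the number of sequences explained the higher diversity of bone marrow, diversity should fall with it within a tissue. Such a fall was not seen. Within the spleen, rho with the logarithm of the sequence number was 0.182 (permutation p = 0.595). Pearson r was 0.150 (permutation p = 0.665), and 0.159 without the 2 farthest of 11 libraries. In bone marrow rho was 0.406 (permutation p = 0.191). Pearson r was 0.291 (permutation p = 0.358), and 0.302 without the 2 farthest of 12. So few libraries cannot exclude a fall. Among the unadjuvanted libraries other than spleen OVA alone 4, the difference was 54.6 effective clones (88.9 ± 23.9, n = 6, and 34.2 ± 5.79, n = 4) and lost its call at the smallest p that so few libraries can give. Of those 4 spleen libraries, the 3 with PBS had 89.1% of their sequences in clones found under another number, whereas OVA alone 6 had 8.36% and still only 38.0 effective clones, below the lowest bone marrow library (54.6), and spleen CpG 12, with 0.665%, had 55.4. Diversity was thus low in 2 spleen libraries with few shared clones, but 2 are too few to exclude shared clones, and a difference of the tissues and the numbers of IgG cells and their RNA content, which were not measured, stay open too.

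Other splits of the libraries were refitted in edgeR for the IGHV counts. With 0 called genes every split gives as many by construction, so the counts of splits hold no evidence and chance could not be excluded between tissues (100 of 100 splits; highest other 1), for adjuvant in bone marrow (100 of 100; highest other 1) or for adjuvant in the spleen (100 of 100; highest other 2). The 10 splits were too few for CpG against Alum in bone marrow (10 of 10; real 0, highest other 0) and in the spleen (10 of 10; real 0, highest other 1) and for OVA alone against PBS in bone marrow (10 of 10; real 0, highest other 0). Between IgM and IgG, 1 of 100 splits, the real one, gave 9 genes and the highest other gave 1, but the splits take the libraries as independent, and 3 of the 10 are of adjuvanted bone marrow and share clones. Among the 7 others, 1 of 64 splits, the real one, gave 2 genes and the highest other gave 1. Bone marrow PBS 1 and 2 among them also share clones, so these libraries are not all independent. With a margin of 1 gene, chance cannot be excluded there. For the clonotypes under 10 library numbers, IGHV1-39 with IGHJ2 and AIITTLVAADFDY and IGHV1-76 with IGHJ2 and ARDLYDYSIFDY complete the set.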
